A study of Homo sapiens with 6 samples.

How the data were processed

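RNA of Hep3B cells was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, 3 of a clone carrying the control plasmid pU6 and 3 of clone D20, silenced for SDHB, with groups taken from the sample descriptions. Per the labels' protocols, cells were grown under G418 until nearly confluent, total RNA was extracted from cell pellets, and biotinylated cRNA was made by the standard Affymetrix protocol. The deposited values are intensity values, 1 per probe set and array on a linear scale, which per the submitters' processing notes were made with MAS5. The version and the target of the scaling are not given in the sources used here. The trimmed mean of each array was at least 500 and at most 501.0, and no detection calls were used here.

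Probe sets were named through GEO's platform annotation, updated by Entrez identifier to current symbols of the RefSeq gene table of assembly GRCh38.p14, which was otherwise used only for the order of neighbouring genes. Of the 54675 probe sets, 41091 that are not controls had 1 gene symbol, 1801 had several and 11777 were not listed there, 41043 being updated to a current symbol. A probe set with several symbols or none was tested but not named. Probe sets of SDHB were not among those named, and its level is not reported here. No reference genome was used.

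Signals were transformed to log2(signal + 16), so the fold change of a dim gene is understated. The 62 control probe sets and the 40% of the others with the lowest mean over all 6 arrays, 21845 probe sets with a mean below a signal of 43.2 on the back-transformed scale, were left out, which left 32768. No further normalization between arrays was applied. Clone D20 was compared with the control clone by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. All 6 arrays entered the fit with no covariate. A difference between single values of 3 arrays against 3 was tested by a two-sided exact permutation test, whose smallest possible p is 0.1.

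A gene was represented by its brightest tested probe set over all arrays, taking those not marked as able to match several families first. The named genes are the members of the complex II list, the 12 largest rises and the 12 largest falls among called genes whose arrays separated by clone and whose mean in the higher clone was above the median of all probe sets tested, up to 4 called members of each list with the largest changes, HIF1A, EPAS1 and VHL, and ACTB and GAPDH. A further gene of that rule is not analysed here. The 36 lists held 852 genes, of which 782 were named on the array and 710 tested. They covered complex II, complex I, complexes III and IV, ATP synthase, the tricarboxylic acid cycle, glycolysis, HIF targets, antioxidant genes, hepatocyte secreted proteins, hepatocyte factors and enzymes, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, proliferation, cell-cycle inhibitors and related genes, apoptosis, integrins, junctions, mesenchymal markers, the extracellular matrix, interferon response, NF-kB targets, TGF-beta and BMP targets, Wnt targets, immediate early genes, 2-oxoglutarate-dependent enzymes, mitochondrial biogenesis, iron, amino acid metabolism, and markers of fibroblasts, blood cells, endothelium and biliary cells. The 34 lists with 5 or more tested genes were compared with the other genes by limma's camera with a preset correlation of 0.01, and Benjamini-Hochberg adjustment over these lists. None of the 13 lists called was called by camera with a correlation estimated per list, the lowest Benjamini-Hochberg adjusted p being 0.09. For some of these lists the estimate lay below the preset 0.01, such as HIF targets (-0.026) and the extracellular matrix (-0.020). For others it lay above, such as complex I (0.14) and hepatocyte secreted proteins (0.11). A higher correlation between genes therefore cannot account for the loss of every call, and the cause was not tested. The test fry asks whether a list's genes move one way on balance, without comparing them to other genes, and called 25 lists.

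The fits were tested on simulated data of 32768 probe sets with 50 probe sets changed at each fold. The share recovered was 28% at 1.5-fold, 60% at 2-fold, 74% at 4-fold and 88% at 8-fold, with 5 unchanged probe sets called. In the data 36.5% of the probe sets tested were called, a far larger share than was changed in the simulation. Benjamini-Hochberg adjustment is stricter where fewer probe sets change, so these shares do not carry over to the data. A list with all of its 17 genes shifted 2-fold lower was recovered and 0 of the other lists were called. The simulated noise was independent between probe sets. The simulation therefore cannot show how often camera calls a list whose genes vary together.

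RNA quality was compared through control probe sets. The ratio of 3' to 5' signal was 1.10 ± 0.042 (SD, n = 3) in the control clone and 1.16 ± 0.080 in D20 for GAPDH (exact permutation p = 0.5), and 1.70 ± 0.25 and 1.52 ± 0.14 for ACTB (exact permutation p = 0.3). The poly-A spike-in controls, which are added to RNA before labelling, had a mean log2 signal of 9.32 ± 0.10 and 9.06 ± 0.02 (exact permutation p = 0.1), and the hybridization controls 12.3 ± 0.064 and 12.5 ± 0.21 (exact permutation p = 0.4).

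The groups, tests, lists, naming rule and all alternatives except the spike-in scaling were set before the data were examined. The alternatives were pseudocounts of 1 and 64, no filter and a filter on the lowest 60%, quantile normalization, median centring, eBayes without trend or robust, leaving out probe sets whose names end in s, x or a (those that can match several transcripts), the replicate letter as a block, each array left out in turn, the mean of a gene's probe sets, an estimated correlation and fry. Scaling each array on its poly-A spike-in controls was added after the data were seen.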

Results

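Gene expression was measured in Hep3B, a human hepatocellular carcinoma cell line, after stable transfection with a plasmid. One clone carried the control plasmid pU6 and the other, D20, carried a construct against SDHB, the iron-sulfur subunit of succinate dehydrogenase (complex II). This enzyme oxidises succinate to fumarate in the tricarboxylic acid cycle and passes the electrons to the respiratory chain. RNA from each clone was hybridised to 3 Affymetrix HG-U133 Plus 2.0 arrays, named A, B and C, which gives 6 arrays in 2 groups. Each array reported a MAS5 signal for 54675 probe sets, of which 32768 were tested, and 26755 of these carried 1 gene symbol and represented 13781 genes. The trimmed mean signal was at most 501.0 and at least 500 on every array and the median signal between 77.5 and 92.2. Pearson's r of log2 signals across probe sets, which are not independent replicates, was 0.954 to 0.957 between control arrays, 0.943 to 0.952 between D20 arrays and 0.908 to 0.919 between arrays of different clones. The number of arrays limits the precision.

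The comparison of the 2 clones asks how gene expression in the cell silenced for SDHB differs from that in its control. The SDHB signal itself was not analysed here, so the silencing was not checked on these arrays. Clone D20 held transcripts at high signal that were dim in the control clone. TUBA1A, an alpha-tubulin, went from a signal of 58.6 ± 21.9 (SD, n = 3) to 21780.3 ± 792.9 (SD, n = 3), and COL1A1, a chain of type I collagen, from 1.23 ± 0.503 to 3780.0 ± 406.8, with the same call from 1 of its 3 other probe sets and a log2 fold change of 3.33 with the mean of its probe sets. The control clone held liver products at high signal that were strongly lower in D20. AFP, the fetal albumin-like protein used as a marker of hepatocellular carcinoma, went from 20569.5 ± 643.3 to 403.5 ± 54.0, and FABP1, the liver fatty acid-binding protein, from 16564.9 ± 1023.5 to 168.7 ± 35.5. SUCNR1, the cell-surface receptor for succinate, went from 9.5 ± 1.8 to 1747.6 ± 46.0.

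The 12 largest rises in log2 fold change, D20 over control, were those of TUBA1A (8.23), COL1A1 (7.78), FEZ1 (7.44), IGFBP2 (6.84), GPX8 (6.69), IGFBP7 (6.65), OLFML2A (6.38), RIPOR3 (6.31), CDC20B (6.16), LOXL2 (6.12), SUCNR1 (6.11) and IL18 (6.08). Among them IGFBP2 and IGFBP7 bind insulin-like growth factors, LOXL2 is a lysyl oxidase that crosslinks collagen, and IL18 is a cytokine of the interleukin-1 family. The 12 largest falls were those of PEG10 (-8.25), MEP1A (-7.43), LYZ (-7.34), FABP1 (-6.51), CADPS (-6.04), AFP (-5.62), A2M (-5.57), CHODL (-5.49), SCGN (-5.37), NTS (-5.28), PDE3A (-5.02) and F2 (-4.94). PEG10 is an imprinted gene expressed from the paternal allele, MEP1A is a subunit of the protease meprin, LYZ is lysozyme, A2M is the protease inhibitor alpha-2-macroglobulin, NTS is the peptide neurotensin and F2 is prothrombin. The standard errors of these 24 differences were between 0.0903 (A2M) and 0.414 (PDE3A). The 3 arrays of one clone lay apart from the 3 of the other for each gene, as the rule for naming them required. Of the 12 rises 8 had a control mean below a signal of 43.2, and of the 12 falls 7 a D20 mean below it, so their size and order depend on the pseudocount. With the pseudocounts of 1 and 64 MEP1A was at -9.22 and -5.75 and PEG10 at -8.96 and -7.15. A smaller change by over 1.5-fold was seen for 13 of the 24 with another choice of probe set, among them A2M at -2.53 with the mean of its probe sets and CADPS at -2.96 and FABP1 at -4.52 without probe sets that can match several transcripts. With the mean of a gene's probe sets FEZ1 was at 4.75, GPX8 at 5.37, IGFBP7 at 5.45, RIPOR3 at 4.66, CDC20B at 4.82, LYZ at -5.10 and PDE3A at -3.86. Outside these 24, ADH4 was then at -2.59, ELOVL6 at -2.64, COL12A1 at 3.11, IFIT2 at 2.01 and INHBA at 2.10. The largest adjusted p among the 24 was 9.7e-07, for PDE3A (limma, Benjamini-Hochberg). LOXL2 did not pass the test when probe sets that can match several transcripts were left out, where another probe set gave a log2 fold change of 1.55 and an adjusted p of 0.06 (limma, Benjamini-Hochberg).

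**Figure D1:**
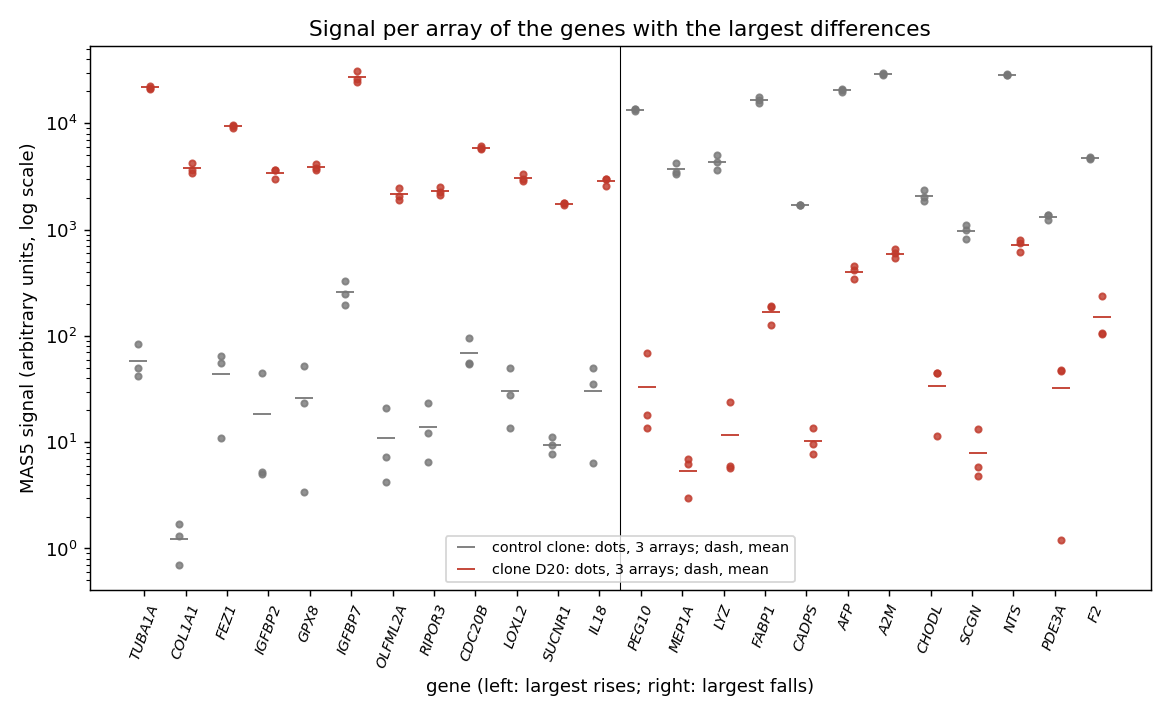
MAS5 signal (arbitrary units, log axis) of the 12 genes with the largest rises and the 12 with the largest falls between the control clone (grey) and clone D20 (red); dots are the 3 arrays of a clone and the dash is their mean. The rule for naming these genes required the 3 D20 arrays to lie apart from the 3 control arrays, as for AFP with means of 20569.5 (control clone) and 403.5 (D20).

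By limma with Benjamini-Hochberg adjustment, 6397 probe sets were higher and 5555 lower in D20, together 36.5% of those tested, and 3025 were at least 2-fold higher and 1951 at least 2-fold lower. At the level of genes 3249 rose and 2852 fell, while 7680 did not pass the test. Of the probe sets called 53.5% were higher in D20, against 42.0% with each array centred on its median and 75.7% with the arrays scaled on the poly-A spike-in controls, which moved the median log2 fold change of all probe sets from 0.03 to 0.27. Each group was a single clone, and nothing in the labels says that the 3 arrays came from separate cultures, so these p-values measure only the spread between arrays of a clone, which may be technical. The silencing and the clone were confounded. Among 3526 called genes with further probe sets, 125 had one called in the other direction.

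Transcripts of complex II and its assembly factors moved in both directions. SDHC, a membrane anchor subunit, had a signal of 3068.0 ± 92.0 (SD, n = 3) in the control clone and 1704.8 ± 346.7 in D20, a log2 fold change of -0.86 ± 0.13 (SE). The assembly factors SDHAF2 (-0.69) and SDHAF3 (-0.95) fell too, and SDHAF4 rose (1.13). SDHA, the flavoprotein subunit, had a log2 fold change of 0.24 (adjusted p = 0.07), SDHD one of 0.12 (adjusted p = 0.42) and SDHAF1 one of 0.28 (adjusted p = 0.072, limma with Benjamini-Hochberg), none of which passed the test. SDHA passed it with quantile normalization, with the replicate block (adjusted p = 0.046), without D20 replicate A (adjusted p = 0.029) and with spike-in scaling, limma with Benjamini-Hochberg in each. SDHD and SDHAF1 passed it with spike-in scaling, and SDHAF1 with the mean of its probe sets. Of the 7 genes tested, 3 fell and 1 rose, or 3 and 3 adjusted over the list alone, and the list as a whole was not called by camera (Benjamini-Hochberg adjusted p = 0.79). SDHC, SDHAF2 and SDHAF3 each lie in a stretch of neighbouring genes whose median log2 fold change was -0.31, -0.62 and -0.39 respectively.

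In complex I, ATP synthase and the mitochondrial ribosome and import list more genes fell than rose. Of 33 complex I genes 16 fell and 3 rose (19 and 3 adjusted over the list alone), with NDUFS3 at -0.96, NDUFA5 at -0.87, NDUFV1 at -0.81 and NDUFAB1 at -0.76. Of 15 ATP synthase genes 8 fell and 1 rose (10 and 1 adjusted over the list alone), among them ATP5MC1 (-0.91), ATP5F1B (-0.81) and ATP5F1D (-0.71), while ATP5F1C rose (0.65). Of 33 genes of the mitochondrial ribosome, protein import and mitochondrial biogenesis, 14 fell and 2 rose (15 and 2 adjusted over the list alone), with the largest falls in FIS1 (-1.78), which acts in mitochondrial fission, TOMM22 (-1.15, or -0.54 with the mean of its probe sets), ESRRA (-0.93) and POLRMT (-0.74), the mitochondrial RNA polymerase. Camera with Benjamini-Hochberg adjustment called complex I (adjusted p = 8.3e-04, and adjusted p = 0.29 with an estimated correlation), ATP synthase (adjusted p = 0.0059, and adjusted p = 0.17 with an estimated correlation) and the mitochondrial ribosome and import list (adjusted p = 0.0026, and adjusted p = 0.17 with an estimated correlation) as lower. Spike-in scaling moved most genes by a similar amount, and the 3 medians with them to 0.01, -0.02 and 0.03. Their distance from the median of all probe sets went from -0.27, -0.31 and -0.25 to -0.26, -0.29 and -0.24, and camera did not call them there (Benjamini-Hochberg adjusted p = 0.059, 0.14 and 0.059). With that scaling 5 complex I genes fell and 4 rose, and 3 ATP synthase genes fell and 1 rose. Without it the 3 medians lay at percentiles 7.73, 7.84 and 6.27 of random lists matched on mean level. Of 18 genes of complexes III and IV and cytochrome c, 7 fell and 2 rose, also adjusted over the list alone, with UQCR10 at -0.85, COX8A at -0.43, CYCS at -0.39 and UQCRQ at 0.43 (camera, Benjamini-Hochberg adjusted p = 0.081). The list was called lower without D20 replicate B (adjusted p = 0.019), with median centring (0.021) and with no filter (0.045), by camera with Benjamini-Hochberg. With spike-in scaling 1 of its genes fell and 4 rose, with a median log2 fold change of 0.10 against -0.16 (camera, Benjamini-Hochberg adjusted p = 0.68). COX8A and CYCS did not pass the test with spike-in scaling, UQCR10 did not without probe sets that can match several transcripts and UQCRQ did not without the variance trend. ATP5F1C did not pass it with quantile normalization or median centring, without control replicate C (log2 fold change 0.51), without D20 replicate A (0.66) or without D20 replicate C (0.58). The ATP synthase call was lost without probe sets that can match several transcripts (adjusted p = 0.4) and outside the stretches of neighbouring genes shifted together (adjusted p = 0.086, median -0.18 against -0.28), by camera with Benjamini-Hochberg.

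In the tricarboxylic acid cycle outside complex II, 10 of 22 genes fell and 4 rose, also adjusted over the list alone. With spike-in scaling 5 fell and 6 rose, and the list's median log2 fold change went from -0.18 to 0.07. MDH2 (-1.09), which makes oxaloacetate from malate, PDHX (-0.98), of the pyruvate dehydrogenase complex, and PC (-0.77), pyruvate carboxylase, fell, and IDH2 rose (1.14). Camera did not call the list (Benjamini-Hochberg adjusted p = 0.15), and PC did not pass the test with spike-in scaling or without the variance trend. Glycolysis genes moved apart, with ENO2 (3.29), PFKFB3 (2.46) and PFKP (2.36) higher and ALDOC (-2.89) lower. Of 22 genes 5 rose and 7 fell, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.46). The list's median log2 fold change was 0.08 and its camera direction was down. PFKP was dim, and at the smaller pseudocount another of its probe sets was the brighter one and had a log2 fold change of -0.63. It did not pass the test with the mean of its probe sets (0.96).

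HIF1A, the oxygen-regulated subunit of hypoxia-inducible factor 1, rose from 10128.4 ± 809.9 (SD, n = 3) to 20108.8 ± 647.3, a log2 fold change of 0.99 ± 0.08 (SE). EPAS1, which encodes HIF-2 alpha, rose by 0.61. VHL, whose product marks both for degradation, had a log2 fold change of -0.10 (limma, Benjamini-Hochberg adjusted p = 0.62). Of 32 HIF targets outside glycolysis 17 rose and 4 fell (17 and 5 adjusted over the list alone). P4HA2 (2.29), a collagen prolyl hydroxylase, and ADM (2.02), adrenomedullin, rose, and LOX (-2.43) and PPP1R3C (-2.01) fell. Camera called the list higher (Benjamini-Hochberg adjusted p = 0.034, and adjusted p = 0.17 with an estimated correlation). That call was lost without control replicate A (adjusted p = 0.054), without the variance trend (0.059), with spike-in scaling (0.062), outside the shifted stretches (0.19) and without probe sets that can match several transcripts (0.27), all by camera with Benjamini-Hochberg. The list's median log2 fold change was 0.39, and in these settings 0.44, 0.39, 0.65, 0.33 and 0.28 in that order. Of 30 2-oxoglutarate-dependent demethylases and hydroxylases, enzymes of which succinate is a product, 4 rose and 6 fell (4 and 5 adjusted over the list alone), with ASPH (-1.39), PLOD3 (-0.88) and TET1 (-0.65) lower (camera, Benjamini-Hochberg adjusted p = 0.99). TET1 did not pass the test with the mean of its probe sets (-0.49).

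Among transcripts of proteins that hepatocytes secrete, more were lower than higher in D20. Of 33 genes 22 fell, 15 of them at least 2-fold, and 4 rose (22 and 5 adjusted over the list alone). Besides AFP and F2, the lipocalin APOM fell by 3.64 and transthyretin, TTR, by 2.99 on the log2 scale (camera, Benjamini-Hochberg adjusted p = 1.2e-06, and adjusted p = 0.17 with an estimated correlation). Hepatocyte transcription factors and metabolic enzymes fell in 7 of 20 cases and rose in 4 (8 and 4 adjusted over the list alone). The alcohol dehydrogenase ADH4 (-4.06), the urea cycle enzymes CPS1 (-3.34) and ARG1 (-2.83) fell and the nuclear receptor NR5A2 rose (2.12). Camera did not call the list (Benjamini-Hochberg adjusted p = 0.23). Of 28 genes of amino acid and nitrogen metabolism 17 fell and 4 rose (19 and 4 adjusted over the list alone). Among them were MAT1A (-2.02), GLUL (-1.64), glutamine synthetase, and BCAT1 (-1.59) (camera, Benjamini-Hochberg adjusted p = 3.0e-04, and adjusted p = 0.12 with an estimated correlation).

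Cholesterol synthesis was the list with the lowest camera p. Of 17 genes 14 fell, 13 of them at least 2-fold, and none rose (15 and 0 adjusted over the list alone). STARD4 (-2.77), DHCR7 (-2.32), INSIG1 (-2.31) and SQLE (-1.93), squalene epoxidase, fell most (camera, Benjamini-Hochberg adjusted p = 1.7e-10, and adjusted p = 0.09 with an estimated correlation). In fatty acid synthesis and lipid storage 10 of 22 genes fell and 1 rose, also adjusted over the list alone. FABP1, ELOVL6 (-3.30), GPAM (-2.37) and FASN (-1.68), fatty acid synthase, were lower (camera, Benjamini-Hochberg adjusted p = 0.0026, and adjusted p = 0.13 with an estimated correlation). Its median log2 fold change was -0.12 and its mean -0.83, and with spike-in scaling the median was 0.13 with the list still called lower. Without probe sets that can match several transcripts it was not called (camera, Benjamini-Hochberg adjusted p = 0.1). Fatty acid oxidation and ketogenesis had 4 of 19 genes higher and 4 lower, also adjusted over the list alone, with ACADL (1.79) and ACAA2 (1.16) higher and BDH1 (-2.39) and ACADM (-0.94) lower (camera, Benjamini-Hochberg adjusted p = 0.26).

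Targets of ATF4, the transcription factor of the integrated stress response, and serine synthesis genes rose in 16 of 30 cases and fell in 4 (18 and 4 adjusted over the list alone). VLDLR (2.11), SESN2 (2.11) and the amino acid transporter SLC7A5 (1.35) rose, and DDIT3, which encodes the stress factor CHOP, fell (-1.60). Camera called the list higher (Benjamini-Hochberg adjusted p = 0.0029, and adjusted p = 0.2 with an estimated correlation), and not without probe sets that can match several transcripts (adjusted p = 0.14). Chaperones of the endoplasmic reticulum were lower, 13 of 18 with 1 higher (15 and 2 adjusted over the list alone). Among them were HSPA5 (-1.13), also known as BiP, SDF2L1 (-0.95), PDIA4 (-0.79) and CRELD2 (-0.76) (camera, Benjamini-Hochberg adjusted p = 3.2e-04, and adjusted p = 0.12 with an estimated correlation). Heat shock proteins had 3 of 11 genes higher and 2 lower, also adjusted over the list alone. HSP90AA1 (0.41) and HSPH1 (0.38) rose, but not without the variance trend, and HSPE1 (-0.71) and DNAJA1 (-0.56) fell (camera, Benjamini-Hochberg adjusted p = 0.99). HSPH1 was at -0.18 without probe sets that can match several transcripts. Antioxidant and NRF2 target genes fell in 11 of 31 cases and rose in 6, also adjusted over the list alone. With spike-in scaling 9 fell and 12 rose, and the list's median log2 fold change went from -0.087 to 0.13. NQO1 (-3.03) and the transporter ABCC2 (-2.47) fell and the aldo-keto reductases AKR1C1 (1.97) and AKR1B10 (1.65) rose (camera, Benjamini-Hochberg adjusted p = 0.24). Iron handling genes fell in 8 of 19 cases and rose in 5, also adjusted over the list alone. Transferrin, TF (-2.37), the iron regulatory protein ACO1 (-1.65) and HJV (-0.87) fell and ceruloplasmin, CP (1.15), rose (camera, Benjamini-Hochberg adjusted p = 0.25). HJV did not pass the test with spike-in scaling, without control replicate C (-0.73) or without D20 replicate A (-0.63), and AKR1C1 did not when no probe set was filtered out.

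Genes of the extracellular matrix and of matrix proteases rose in 19 of 26 cases and fell in 2, also adjusted over the list alone, 13 of the rises being at least 2-fold. COL12A1 (4.02), the urokinase gene PLAU (2.92) and LAMB3 (2.22) rose besides COL1A1 (camera, Benjamini-Hochberg adjusted p = 2.5e-04, and adjusted p = 0.12 with an estimated correlation). TGF-beta and BMP targets rose in 15 of 25 cases and fell in 4 (16 and 5 adjusted over the list alone). LTBP2 (3.14), INHBA (3.04), BMP4 (3.02) and TGFB2 (2.69) rose most (camera, Benjamini-Hochberg adjusted p = 0.0031, and adjusted p = 0.23 with an estimated correlation, and adjusted p = 0.1 without probe sets that can match several transcripts). Inflammatory and NF-kB targets rose in 10 of 20 cases and fell in 4, also adjusted over the list alone, with CXCL8 (4.25) and IL32 (2.73) higher and CXCL5 (-3.42) and CXCL2 (-1.64) lower. Camera called this list (Benjamini-Hochberg adjusted p = 0.032, and adjusted p = 0.17 with an estimated correlation), but not with spike-in scaling (adjusted p = 0.059), without the variance trend (0.071), with the mean of a gene's probe sets (0.077), outside the shifted stretches (0.067) or without probe sets that can match several transcripts (0.45). Its median log2 fold change was 0.54, and in these settings 0.79, 0.54, 0.36, 0.34 and 0.28 in that order, with 9 of 17 genes higher and 4 lower outside the stretches. PLAU did not pass the test without those probe sets (log2 fold change 0.51), and CXCL2 did not when no probe set was filtered out (-0.51).

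Mesenchymal markers rose in 10 of 22 cases and fell in 5, also adjusted over the list alone, with the receptor kinase AXL (3.45), SPARC (3.11) and CCN1 (2.77) higher and NT5E (-4.08, or -2.30 with the mean of its probe sets) lower (camera, Benjamini-Hochberg adjusted p = 0.19). Cell-cell junction and epithelial genes rose in 11 of 20 cases and fell in 4 (11 and 5 adjusted over the list alone), with the epithelial splicing regulator ESRP1 (2.97), PKP3 (1.43), CLDN1 (1.31) and DSC2 (1.02) higher (camera, Benjamini-Hochberg adjusted p = 0.058). The list was called without D20 replicate B (adjusted p = 0.019), with quantile normalization (0.028), with the replicate block (0.043) and with no filter (0.045), by camera with Benjamini-Hochberg. PKP3 did not pass the test without D20 replicate B (log2 fold change 1.30). Integrin and cell-matrix adhesion genes rose in 9 of 22 cases and fell in 4 (10 and 4 adjusted over the list alone), with ITGA5 (2.37), ITGA3 (2.23) and ITGB4 (1.82) higher and PARVA (-2.32, or -1.31 without probe sets that can match several transcripts) lower (camera, Benjamini-Hochberg adjusted p = 0.22).

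Proliferation genes moved in both directions, with 8 of 38 higher and 10 lower (9 and 11 adjusted over the list alone). The cyclins E, CCNE2 (2.15) and CCNE1 (1.25), rose and CCND1 (-1.69) and FOXM1 (-1.03) fell (camera, Benjamini-Hochberg adjusted p = 0.78). CDKN1A, the cell-cycle inhibitor p21, rose from 85.3 ± 56.6 (SD, n = 3) to 3754.4 ± 193.1, a log2 fold change of 5.43. CDKN1C (1.86) rose and CDKN2B fell (-2.78), by over 1.5-fold less with the mean of its probe sets. In that list of cell-cycle inhibitors and related genes 4 of 15 genes rose and 4 fell (4 and 5 adjusted over the list alone), and camera did not call it (Benjamini-Hochberg adjusted p = 0.99). Apoptosis regulators rose in 7 of 19 cases and fell in 1, also adjusted over the list alone, with the BH3-only genes PMAIP1 (2.82), BIK (1.62) and BCL2L11 (1.62) and the survival gene BCL2L1 (1.21) higher (camera, Benjamini-Hochberg adjusted p = 0.058). The list was called without control replicate A (adjusted p = 0.038) or C (0.031), with the replicate block (0.044) and with no filter (0.031), by camera with Benjamini-Hochberg. Interferon response genes rose in 10 of 23 cases and fell in 2 (10 and 3 adjusted over the list alone), with IFIT2 (2.96), TAP1 (1.99) and MX1 (1.58) higher and IFITM2 (-1.33) lower (camera, Benjamini-Hochberg adjusted p = 0.19, and adjusted p = 0.031 with no filter). MX1 did not pass the test without control replicate B (log2 fold change 1.12, limma with Benjamini-Hochberg adjusted p = 0.054), without D20 replicate B (1.27, adjusted p = 0.085) or without the variance trend (adjusted p = 0.051). Immediate early genes rose in 10 of 22 cases and fell in 5 (11 and 5 adjusted over the list alone), with the phosphatase gene DUSP4 (3.31) higher and DUSP6 (-2.61) lower (camera, Benjamini-Hochberg adjusted p = 0.15). Wnt targets fell in 6 of 16 cases and rose in 3, also adjusted over the list alone, with TBX3 (-1.43) lower and TNFRSF19 (3.66) higher (camera, Benjamini-Hochberg adjusted p = 0.43).

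**Figure D2:**
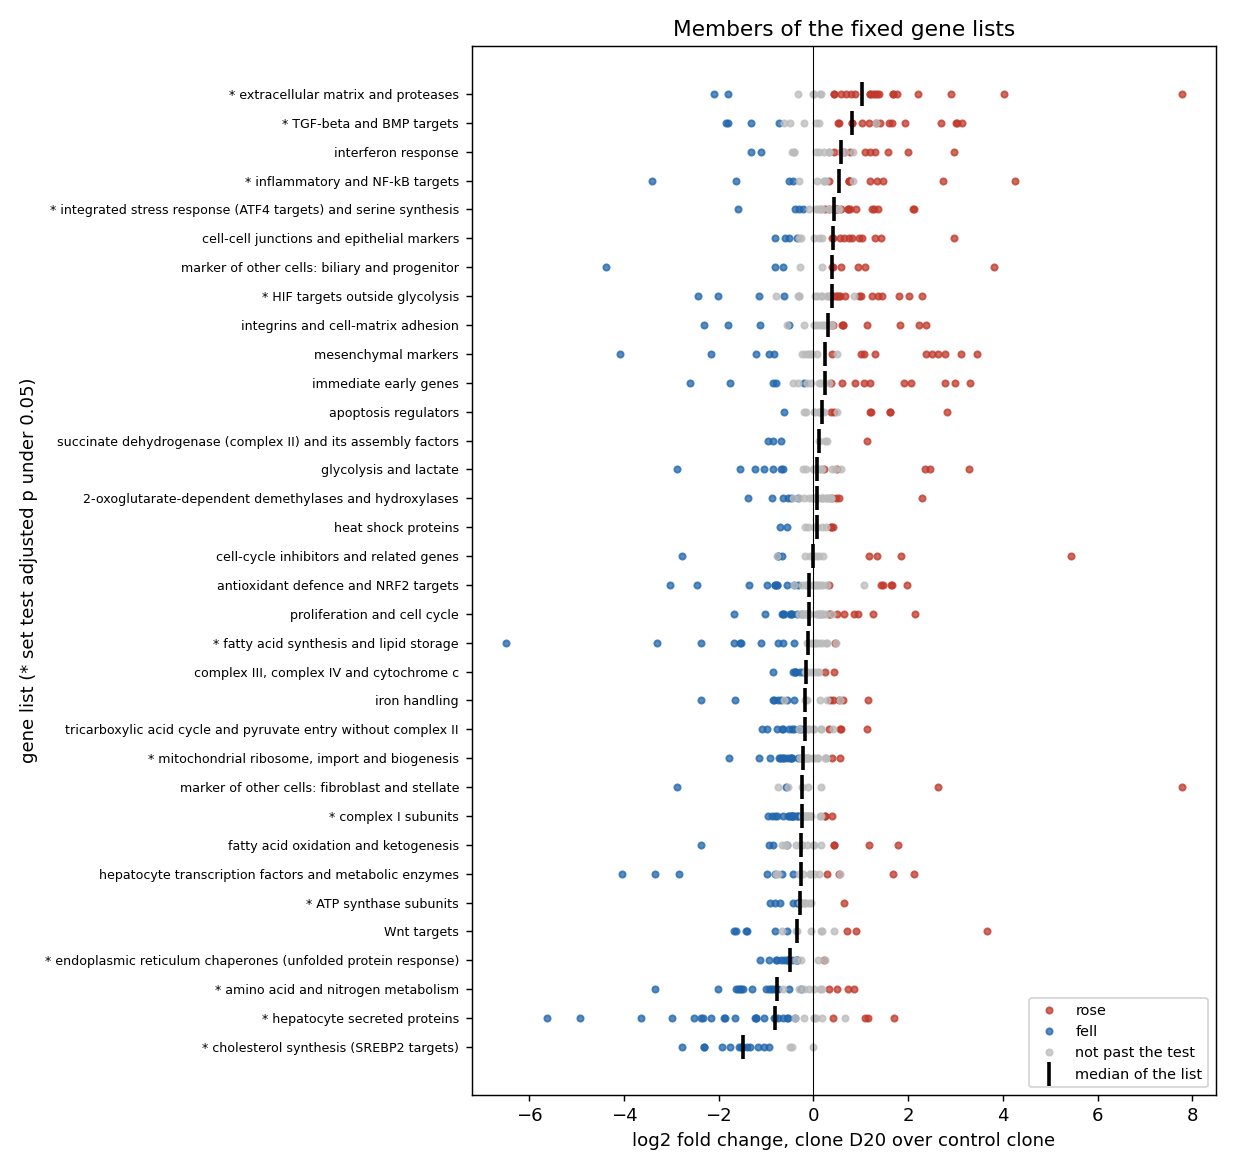
Log2 fold change, clone D20 over control clone, of each tested member of the 34 gene lists tested, 1 list per line, coloured by whether it rose, fell or did not pass the limma test, with the list's median as a black bar; a star marks the 13 lists called by camera. Cholesterol synthesis has the lowest median, -1.49, and the extracellular matrix list the highest, 1.03.

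Markers of other cell types gave mixed values. Of 9 fibroblast and stellate cell markers 2 rose, COL1A1 and, except without probe sets that can match several transcripts (1.22), TAGLN (2.64), and 2 fell, LUM (-2.89) and PDGFRA (-0.58), of which PDGFRA had a second probe set called in the other direction and was not past the test without control replicate A (-0.51) or with spike-in scaling (-0.33) (camera, Benjamini-Hochberg adjusted p = 0.98). Of 11 biliary and progenitor markers 6 rose and 3 fell, with AQP1 (3.81) and PROM1 (0.94) higher and DLK1 (-4.39, or -1.76 without probe sets that can match several transcripts) lower (camera, Benjamini-Hochberg adjusted p = 0.62). The counts of both lists were the same adjusted over the list alone. Blood cell markers had 4 genes tested, LAPTM5 higher (2.83) and LYZ lower, and endothelial markers had 2, PECAM1 higher (1.63), and both lists were too short for camera. Of the reference genes, ACTB had a log2 fold change of 0.28 (limma, Benjamini-Hochberg adjusted p = 0.04) and GAPDH one of 0.04 (adjusted p = 0.8), and the ACTB call was lost without any 1 array except D20 replicate A (adjusted p between 0.084 and 0.13, log2 fold change between 0.19 and 0.29). The direction of GAPDH turned with median centring (-0.082), and ACTB did not pass the test there (0.16), with no filter or without the variance trend.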

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

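The tests of fibroblast transcripts and of a wrong origin were chosen after the results they bear on had been seen.

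Outside the probe sets of the comparison, the ribosomal RNA control probe set for the 5' part was 2.31 times as bright in D20 as in the control clone and the one for the middle part 1.65 times, a signal in data that the comparison did not use (exact permutation p = 0.1 for each, the smallest that 3 against 3 arrays allow). The set for the 3' part of the same RNA was near background, with mean signals of 33.7 ± 38.5 (SD, n = 3) in D20 and 61.8 ± 13.4 in the control clone (exact permutation p = 0.4). Those of the other ribosomal RNA were 1.44 (5' part, exact permutation p = 0.3), 0.978 (middle, exact permutation p = 1) and 1.46 times as bright (3' part, exact permutation p = 0.5).

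Fold changes between the clones ran along chromosomes, and in 87 of 515 windows of 50 neighbouring genes the median log2 fold change was 0.3 or more in size, 33 higher and 54 lower, against at most 16 in 1000 shuffles of gene order. The 30 stretches of such windows held 3000 genes and 1584 of the 6094 called genes placed, and the longest, 400 genes from SBF2 to FAM168A with a median of -0.62, had 225 genes lower and 32 higher. This is consistent with a different number of copies of chromosome stretches in the 2 clones, and the longest stretch holds SDHAF2, NDUFS3, NDUFV1 and F2. Outside the stretches camera still called cholesterol synthesis (Benjamini-Hochberg adjusted p = 6.9e-09), hepatocyte secreted proteins (3.2e-07) and complex I (0.0064). Also still called were fatty acid synthesis and amino acid metabolism (1.8e-04 each), the extracellular matrix (7.4e-04) and TGF-beta and BMP targets (7.6e-04). The same held for endoplasmic reticulum chaperones and the mitochondrial ribosome and import list (7.9e-04 each) and the integrated stress response (0.015). Integrins (0.015) and immediate early genes (0.04) were newly called. The calls of HIF targets (0.19, median 0.33 against 0.39 with all genes), ATP synthase (0.086, -0.18 against -0.28) and NF-kB targets (0.067, 0.34 against 0.54) were lost. Fewer genes were left in these lists. The stretches were chosen by these same fold changes, so the new calls are no independent support. Outside them 7 integrin genes rose and 0 fell, against 9 and 4 with all genes. With an estimated correlation no list was called outside the stretches (lowest adjusted p = 0.11, camera with Benjamini-Hochberg), and a biological effect of the silencing on whole regions stays open as untested.

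In 45 genes the signal was bright in one clone and dim in the other, 35 bright in D20 and 10 in the control, against 0 in each of the 9 other splits of the arrays. Those splits mix arrays of both clones, so a gene that differs only between the clones cannot count in them. That 0 is thus no measure of chance. Only 7 of the 45 lay in a shifted stretch of their direction, which argues against the copy number of such long stretches as their shared cause. Gains or losses of single genes would not show in windows of 50 genes. Whether the 45 genes lay beside each other more often than by chance was not tested. Of the abundant fibroblast transcripts 2 of 4, COL3A1 (20.3) and LUM (8.30), were below a signal of 43.2 on all D20 arrays. The bound asked for only 1 such transcript and was set when LUM was already a named fall, so meeting it decides nothing. In the control clone COL3A1 was as dim (20.2) and LUM brighter (160.4). COL1A2 had 84.2 ± 48.3 (SD, n = 3) in D20 and 68.5 ± 16.2 in the control clone, and DCN 37.6 and 74.0. These values show only that the 4 transcripts were not clearly raised in D20. A mislabelled culture or a clone of other origin cannot be told apart from the silencing by these 45 genes, because no marker of origin was fixed and each group was 1 clone, and an effect of SDHB loss stays open too.

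In the complex I, ATP synthase and mitochondrial biogenesis lists more genes fell (16 of 33, 8 of 15 and 14 of 33) than rose (3, 1 and 2), with list medians of -0.25, -0.28 and -0.22. With an estimated correlation none of the 3 was called (camera, Benjamini-Hochberg adjusted p = 0.29, 0.17 and 0.17). Among 10000 random lists matched on mean level these lay at percentiles 7.73, 7.84 and 6.27, and the matched lists had medians of -0.097, -0.079 and -0.053, so a shift of bright genes as a class may account for some of the fall. By the rule set beforehand, the 3 medians would have had to lie below -0.27, -0.31 and -0.24 to reject that explanation, and none did. Scaling on the poly-A spike-ins moved most genes by a similar amount, the median of all probe sets from 0.03 to 0.27, and the distance of the 3 list medians from it went from -0.27, -0.31 and -0.25 to -0.26, -0.29 and -0.24. It bears mainly on whether these genes fell at all. Their place below the others changed little, but camera, which tests that place, did not call the lists with that scaling (Benjamini-Hochberg adjusted p = 0.059, 0.14 and 0.059). The amount of spike-in added is not given in the sources used here. Why the calls ended with that scaling was not tested, and an effect of the silencing stays open.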

How the results depend on the processing

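Spike-in scaling was chosen after seeing the data. Of 160 named genes 133 kept direction and side of the threshold in every setting in which they were tested and 5 reversed in at least one. Of 34 lists 4 did and 7 reversed, counted by the direction of the list's test, which its median need not follow. The settings counted include the estimated correlation, which took the call from all 13 lists called, and fry, which called 11 further lists. These change the test rather than the processing, so no list called could be among the 4. Of the 160 genes 54 had a fold change smaller by over 1.5-fold in some setting, 28 of them by the choice of probe set. Without probe sets that can match several transcripts, 3592 were higher, 3280 lower and 1842 at least 2-fold higher, and 7 lists were called, with 20281 probe sets tested. With spike-in scaling 9648 were higher, 3097 lower and 1248 at least 2-fold lower, and 8 lists were called. With the lowest 60% left out 1991 were at least 2-fold higher, with fewer probe sets tested. An estimated correlation called 0 lists and fry 25. Reversed values were PFKP -0.63 with a pseudocount of 1, HSPH1 -0.18 and VHL 0.32 without the multiply matching probe sets, VHL 0.15 with spike-in scaling, PDGFRA 0.71, VHL 0.11 and GAPDH -0.018 with the mean of a gene's probe sets, GAPDH -0.082 with median centring and -0.054 without D20 replicate B, and the biliary list, whose median of 0.39 stood against a downward fry test. The other reversed lists were called neither before nor after. Their medians were 0.39 for glycolysis and 0.089 for proliferation without the multiply matching probe sets, -0.048 for proliferation with quantile normalization, 0.16 with spike-in scaling and -0.10 with fry. For heat shock they were 0.067 with the lowest 60% left out and with the replicate block, 0.052 with quantile normalization, 0.33 with spike-in scaling, 0.088 without control replicate B and 0.14 without D20 replicate A. For cell-cycle inhibitors and related genes they were -0.013 with a pseudocount of 1 and without the variance trend, -0.039 with no filter and without the multiply matching probe sets, -0.13 with median centring, -0.055 without control replicate B and -0.0056 without D20 replicate A. For 2-oxoglutarate-dependent enzymes they were 0.074 with a pseudocount of 1, without the variance trend and with fry, 0.068 with the lowest 60% left out, 0.33 with spike-in scaling, 0.051 without control replicate A, 0.092 without D20 replicate A and 0.10 without D20 replicate C. For fibroblast markers they were -0.23 without the variance trend, -0.0034 with spike-in scaling and -0.39 without D20 replicate B. Over all 6 fits without 1 array, reversed or not, the medians were 0.022 to 0.14 for heat shock, -0.055 to 0.069 for the inhibitors, 0.045 to 0.10 for the 2-oxoglutarate-dependent enzymes and -0.48 to -0.12 for fibroblast markers. The cause was not tested. Leaving out 1 array gave 5312 to 5884 higher, 4398 to 5431 lower and 13 to 15 lists. Letters did not pair the arrays (r of deviations -0.02, 0.05 and 0.01), and the replicate block gave 6658 higher, 5899 lower, 3037 and 1960 at least 2-fold, and 15 lists. Genes with signals near 43.2 are limited by background.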

Other observations

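Of 22 imprinted genes tested 7 fell and 6 rose. Besides PEG10 and DLK1, PEG3 fell from a signal of 4127.1 to 139.0 (log2 fold change -4.75) and its antisense transcript PEG3-AS1 by 3.59 on the log2 scale, and SGCE, the neighbour of PEG10, by 1.99. CDKN1C, a maternally expressed inhibitor of the cell cycle, rose (1.86), as did KCNQ1 (2.02), while KCNQ1OT1, the antisense transcript of that region, fell (-1.72). PEG3, PEG3-AS1, SGCE, KCNQ1 and KCNQ1OT1 were chosen after their values were seen.

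A hypothesis drawn from PEG10, PEG3 and DLK1 was that imprinted genes as a class change by more than other genes of like level. It was tested on the 17 imprinted genes whose values had not been looked at when the test was set, SGCE, KCNQ1 and KCNQ1OT1 among them. Of these 5 rose and 3 fell (limma, Benjamini-Hochberg), and their median absolute log2 fold change, 0.62, lay at percentile 85.3 of 10000 lists matched on mean level, whose median was 0.45 and 95th percentile 0.71. The test did not decide the hypothesis, since the value lay between both bounds set for it. The matched lists also do not allow for neighbouring genes that change together, such as SGCE beside PEG10, whose value had been seen. CDKN1C (1.86) and DLK1 (-4.39), which are members of the fixed gene lists, lay in shifted stretches of the other direction, with medians of -0.43 and 0.34. Whether PEG10, SGCE, KCNQ1OT1 and MEST lay in stretches of their own direction is not given here. CDKN1C and DLK1 therefore do not show that the imprinted genes as a class went against their regions.

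Other genes bright in D20 alone, chosen after their values were seen, were the desaturase gene SCD5 (log2 fold change 6.08), the keratin KRT80 (5.79), MFAP4 (5.65), of elastic fibres, the secreted protease HTRA1 (5.13) and the cancer-testis gene MAGEA6 (4.84). Bright in the control clone alone were the pluripotency factor SOX2 (-4.25) and the phospholipase PLA2G7 (-4.75).

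The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 11952 probe sets and 13 lists, and was the 1 division of the 10 with as many probe sets and the 1 with as many lists. The others called 0 probe sets each, with 375 to 670 at an unadjusted p under 0.05 by limma, and 1 to 7 lists. They mix arrays of both clones, so the difference between the clones widens the spread within their groups. They therefore cannot show how many probe sets would be called by chance.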
